A study of Mus musculus with 20 samples.

How the data were processed

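The authors deposited 1 table of raw read counts per organ, with a column per sequencing run and a row per Ensembl gene. The deposited values were whole numbers with a different total per column and carried no normalization. Per the labels, RNA was amplified with SMART-Seq v4 and libraries were made with an Ovation kit. Per the submitters' processing notes, TopHat2 and HTSeq were used with the mouse genome GRCm38/mm10, and neither versions, an annotation release nor a strand setting were stated. The brain and kidney tables also held 5 summary lines of the counting tool, which were left out. Gene symbols and positions came from the GENCODE M21 annotation (GRCm38), which covered 45143 of 46078 genes (97.97%). The genes without a symbol held 0.047% of the counts. For 112 genes that share a symbol the Ensembl identifier was kept.

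The labels list 20 runs, and heart at 3 months and kidney at 24 months have 4 where the other groups have 3. In heart, title and description name 1 library on 2 lanes. In kidney, the titles name another library as repeated than the descriptions do. A Pearson chi-square per degree of freedom between the runs, over genes with at least 20 counts, was 1.085 for the heart pair and 1.066 for the kidney pair of the descriptions. It was 61.2 to 202.8 for 22 pairs of different libraries. The runs of each such pair were summed, which gave 18 libraries, and libraries were numbered 1 to 3 within each group by their labels. For 1 run of the summed heart library the age field says 4 months and the title says 3, and it was kept at 3 months.

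Each organ was fitted alone for the effect of age, and all 6 groups were fitted together for organ comparisons and for differences of age effects. Genes were kept by filterByExpr (minimum count 10), scaled by TMM factors and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. No replicate term was used, since the labels do not say what a number shares. CPM values were scaled within the fit they belong to. A fold against a group with 0 counts is a bound against 3 counts over the group. The count of DESeq2 1.42.0 (Wald test, default settings) is given beside that of edgeR.

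For gene lists, 46 lists of cell type markers, vessel functions, signalling pathways, immune response, metabolism, stress and sample make-up were tested per organ with camera of limma 3.58.1. It was run with a preset correlation of 0.01 and with a correlation estimated from the data, and adjusted over the lists of the organ. The rotation test fry was run as an alternative. In heart 12 lists passed with the preset correlation, and the report gives some of them. Tests, lists, alternatives and the rule for naming genes were chosen before the data were examined, apart from those said to be chosen later. The rule named, per age comparison, up to 10 genes in each direction past the threshold with no overlap between the ages and a mean of at least 1 CPM, and up to 4 genes of each list discussed. It also named a fixed set of sorting, ageing and vessel genes, of which 1 is not reported here and was left out of the named genes after the analysis, and for organ comparisons and differences the 5 largest in each direction. Predicted genes, immunoglobulin segments and ribosomal protein genes were left out of the largest changes.

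Before use, each test was run on simulated counts with the means and spread of the data, in which 100 genes were changed 2-fold and 100 genes 4-fold. In heart, brain and kidney edgeR recovered 16%, 25% and 21% of 2-fold changes and 54%, 64% and 67% of 4-fold changes. Its false calls numbered 4, 5 and 12, which was 5.4%, 5.3% and 12% of its calls. DESeq2 recovered 40%, 52% and 46% of 2-fold changes, and 42.2%, 36.8% and 44.3% of its calls were false. The MHC class II list, changed 2-fold, was called by camera with the preset correlation in each organ (adjusted p 0.00461, 0.00138 and 6.1e-14) and in 0 of 3 organs with an estimated correlation (0.950, 0.973 and 0.0535). Other lists called in these simulations numbered 0, 0 and 1. Genes were drawn independently of each other, so the simulations could not show false calls of lists whose genes vary together.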

Results

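Bulk RNA sequencing measured gene expression in endothelial cells, the cells that line blood vessels, from the heart, brain and kidney of male C57BL/6 mice aged 3 or 24 months. Per the labels, tissue was digested with collagenase, cells carrying CD31 (the endothelial surface protein encoded by Pecam1) were held on magnetic beads, and CD31 positive cells without GP38 or CD45 were then sorted. GP38, encoded by Pdpn, marks fibroblasts and lymphatic vessels, and CD45, encoded by Ptprc, marks leukocytes. The deposited values were raw read counts per gene for 46078 genes in 20 sequencing runs of 18 libraries, 3 libraries in each of 6 groups. The total count per library was 38783581 to 87598835 in heart at 3 months, 38338152 to 44359038 in heart at 24 months, 42161982 to 43581356 in brain at 3 months, 39155805 to 60492548 in brain at 24 months, 38189089 to 42083684 in kidney at 3 months and 38192446 to 80960468 in kidney at 24 months. Levels are given as CPM, counts scaled to a common library total by TMM, with the standard deviation (SD) over the libraries of a group, n = 3, and fold changes on the log2 scale, 24 over 3 months, with a standard error (SE). The labels do not say that the libraries of a group come from separate animals, so each p-value measures the spread between libraries. Floors and bounds cover counting error only.

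The libraries differed by organ far more than by age. The median correlation of log2 CPM, across genes, which are not independent replicates, was 0.962 for 18 pairs of libraries of 1 group. It was 0.956 for 27 pairs of the same organ and the other age, and 0.816 for 108 pairs of different organs. Pecam1 was abundant in every group, with 1645 ± 203.5 CPM in young heart, 1335 ± 212.0 CPM in young brain and 1347 ± 114.4 CPM in young kidney. Ptprc, the gene of the leukocyte protein removed by the sort, was at 2.75 ± 2.65 CPM in young heart, 2.47 ± 3.69 CPM in young brain and 7.10 ± 4.23 CPM in young kidney. Some genes set libraries with replicate number 1 apart in every group. Zbtb16, a transcription factor gene induced by glucocorticoid hormones, was at 74.0 CPM in number 1 and at 12.9 and 14.4 CPM in the others of young heart, and number 1 was also the highest of its group in the other 5 groups. With group and number as terms of 1 edgeR fit, 143 of 18369 genes differed between the numbers, 118 of them higher in number 1, a comparison chosen after its values were seen.

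**Figure D1:**
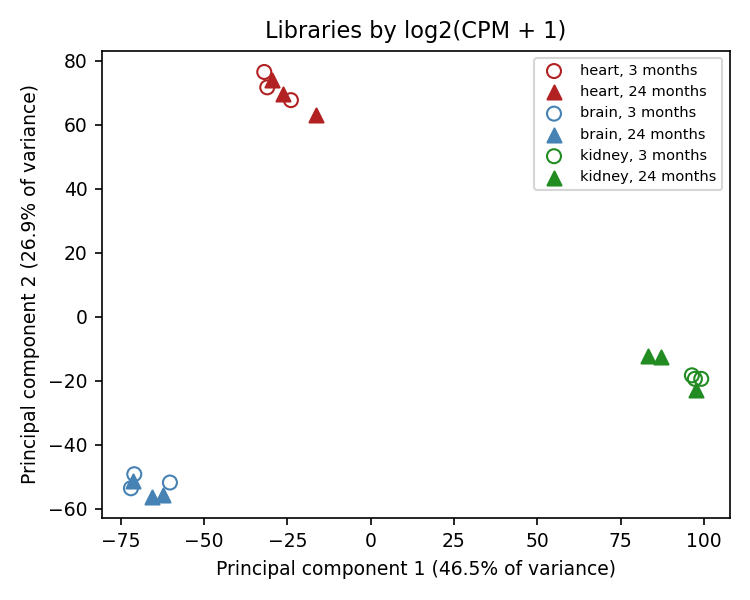
Principal components of log2 CPM of the 18 libraries, each point a library, with colour for the organ and filling for the age (open, 3 months; filled, 24 months). Component 1 (x axis, 46.5% of the variance) and component 2 (y axis, 26.9%) part the 3 organs, and the ages of each organ overlap.

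The endothelium of each organ was first compared at 3 months, to describe organ identity in young animals. The transporter and barrier genes of brain vessels set the brain apart. All 22 genes of a blood-brain barrier list were lower in heart than in brain past the threshold over all genes tested (22 adjusted over the list alone; median log2 fold change -7.04; camera adjusted p 1.7e-65), and the list held with adjusted p = 1.5e-05 with an estimated correlation. Of the same list, 21 of 22 genes were higher in brain than in kidney (median 6.69; camera adjusted p 1.7e-56; adjusted p = 0.000138 with an estimated correlation). Mfsd2a, a lipid transporter of brain capillaries, was at 761.8 ± 64.7 CPM in brain and at 0.0925 ± 0.160 CPM, 11 counts, in kidney. Bche, which encodes the esterase butyrylcholinesterase, was at 65.3 ± 23.7 CPM in brain and had 0 counts in heart, at least 3691-fold higher against a floor of 3 counts over the group. Ddc, which encodes an enzyme of dopamine and serotonin synthesis, was at 219.8 ± 77.7 CPM in brain and at 0.0250 ± 0.0434 CPM, 3 counts, in heart.

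Heart libraries held genes of heart muscle and of capillaries that take up fatty acids, and RNA of heart muscle cells was not told apart from endothelial expression. Mb, which encodes myoglobin of muscle, was at 25.9 ± 6.57 CPM in heart and had 0 counts in kidney, at least 1108-fold higher. Gata4, a cardiac transcription factor gene, was at 23.3 ± 8.14 CPM in heart and had 0 counts in kidney, at least 995.2-fold higher. Pcsk6, which encodes a proprotein-cleaving enzyme, was at 27.7 ± 7.85 CPM in heart and had 0 counts in brain, at least 1130-fold higher. Of 12 capillary genes, 9 were higher in heart than in brain (median log2 fold change 4.80; camera adjusted p 4.8e-30; adjusted p = 1.5e-05 with an estimated correlation). Of 14 tested cardiomyocyte genes, 10 were higher in heart than in brain (median 8.13; camera adjusted p 4.6e-08; adjusted p = 0.00312 with an estimated correlation). Their summed level in heart was 184.8 ± 42.8 CPM, beside 14750 ± 1434 CPM for the pan-endothelial list.

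Kidney libraries held genes of kidney endothelium together with genes of kidney tubules. Of 16 kidney endothelial genes, 13 were higher in kidney than in heart (median log2 fold change, heart over kidney, -2.80; camera adjusted p 4.6e-15; adjusted p = 0.00112 with an estimated correlation). Of 17 renal tubule genes, 14 were higher in kidney than in heart (median -8.64; camera adjusted p 8.5e-06; adjusted p = 0.177 with an estimated correlation). The tubule list summed to 12920 ± 789.1 CPM in kidney, 47.3 ± 40.8 CPM in heart and 60.5 ± 78.9 CPM in brain. Ren1, the renin gene of juxtaglomerular cells, was at 139.2 ± 49.9 CPM in kidney and had 0 counts in brain, at least 5682-fold higher. Casr, the calcium-sensing receptor gene of tubules and parathyroid, was at 81.3 ± 9.07 CPM in kidney and had 0 counts in brain, at least 3318-fold higher. Prom2, an epithelial membrane gene, was at 41.9 ± 8.68 CPM in kidney and had 0 counts in heart, at least 2369-fold higher.

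In edgeR, 2466 of 18369 genes passed an adjusted p of 0.05 between heart and brain (1268 higher in heart, 1198 in brain), of which 1803 differed over 2-fold. Between heart and kidney 3407 genes passed (1355 higher in heart, 2052 in kidney), and between brain and kidney 3700 (1482 higher in brain, 2218 in kidney). The adjusted p of the genes printed above, of those picked by the naming rule, ranged up to 0.00142 (0.0321 over all that the rule picked), and all 3 libraries of the higher group lay above all 3 of the lower group. With simulated counts of this spread the test recovered 23% of 2-fold changes between heart and brain, so many smaller differences would be missed.

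Age was then compared within each organ, which asks how the endothelium of that organ changes between young and old mice. In heart, genes of pericytes and smooth muscle, the cells that wrap vessels, were lower at 24 months. All 14 genes of the list were lower (median log2 fold change -0.86; camera adjusted p 6.4e-11; adjusted p = 0.536 with an estimated correlation), and 3 of 14 passed adjusted over the list alone. Rgs5 (ENSMUSG00000026678, GRCm38/mm10 chr1:169655501-169695813), a signalling regulator of pericytes, was at 992.5 ± 253.6 CPM at 3 months and 418.3 ± 142.3 CPM at 24 months (log2 -1.25, SE 0.28). Pdgfrb, the platelet-derived growth factor receptor gene by which pericytes are recruited, was at 207.1 ± 63.3 CPM and 67.5 ± 35.8 CPM (log2 -1.62, SE 0.40). Kcnj8, a potassium channel gene of pericytes, was at 15.1 ± 1.60 CPM and 6.97 ± 1.25 CPM. For all of Rgs5, Pdgfrb and Kcnj8 the 3 older libraries lay below the 3 younger ones. The summed level of the list was 3304 ± 1058 CPM at 3 months and 1769 ± 331.1 CPM at 24 months. RNA of pericytes and smooth muscle cells left in the sorted libraries was not told apart from endothelial expression.

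Genes of the basement membrane, the collagen and laminin sheet under the endothelium, were also lower in old heart. Of 34 genes of the list, 28 were lower (median -0.41; camera adjusted p 6.4e-11; adjusted p = 0.550 with an estimated correlation), and 3 passed adjusted over the list alone. Mmp14, which encodes a membrane-bound protease that cleaves matrix, was at 71.1 ± 21.3 CPM at 3 months and 20.1 ± 3.07 CPM at 24 months (log2 -1.82, SE 0.27). Col18a1, the gene of the collagen that releases endostatin, was at 207.9 ± 28.2 CPM and 94.5 ± 19.1 CPM (log2 -1.14, SE 0.19). Col4a1, the gene of the main basement membrane collagen, was at 4137 ± 1688 CPM and 2182 ± 115.3 CPM (log2 -0.92, SE 0.26). Library 1 of young heart held the most Col4a1, 6068.8 CPM against 3398.4 and 2944.8 CPM. Without that library the matrix list had a median of -0.268 (camera adjusted p 2.3e-06) and the pericyte list a median of -1.095 (camera adjusted p 2.2e-17). Of 10 fibroblast genes in old heart, 7 were lower and 3 higher (median -0.787; camera adjusted p 0.0575; adjusted p = 0.651 with an estimated correlation). Col1a2, a fibrillar collagen gene, was at 45.6 ± 5.84 CPM and 15.3 ± 5.54 CPM, while Dcn, a matrix proteoglycan gene, was at 47.2 ± 20.5 CPM and 128.4 ± 29.5 CPM. For the matrix and fibroblast lists, RNA of pericytes or fibroblasts was not told apart from endothelial expression.

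Antigen presentation genes were higher in old heart. All 8 genes of the MHC class II list, which present peptides to helper T cells, were higher (median log2 fold change 1.46; camera adjusted p 7.8e-10; adjusted p = 0.536 with an estimated correlation), and 3 of 8 passed adjusted over the list alone. H2-Ab1, a class II chain gene, was at 26.6 ± 6.60 CPM at 3 months and 69.7 ± 30.4 CPM at 24 months (log2 1.39, SE 0.34). Ciita, the transcription activator of class II genes, had 1 count over the 3 young libraries, 0.00367 ± 0.00635 CPM, and 2.45 ± 1.06 CPM at 24 months. The class I list was higher as well, 15 of 16 genes (median 0.26; camera adjusted p 0.000601; adjusted p = 0.651 with an estimated correlation). The leukocyte list summed to 78.9 ± 8.37 CPM and 93.4 ± 41.1 CPM. Library 2 of old heart held the most of the class II list (517.4 CPM) and of the leukocyte list (137.6 CPM). Library 2 of young heart held the most class II (221 CPM) but the least of the leukocyte list (69.3 CPM). RNA of leukocytes was not told apart from endothelial expression. Cell cycle genes were lower, 26 of 27 (median -0.40; camera adjusted p 0.00125; adjusted p = 0.663 with an estimated correlation), but without library 1 of young heart the list's adjusted p was 0.158. Rrm2, which encodes an enzyme of DNA precursor synthesis, was at 23.7 ± 5.60 CPM and 8.67 ± 3.84 CPM.

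Gene by gene, the spread between heart libraries left none of the 15002 tested genes past the threshold: edgeR called 0, with 843 at an unadjusted p under 0.05 where chance gives 750, and with 0 also when number 1 was a term. The lowest adjusted p in heart was 0.448, shared by Mmp14. DESeq2 called 170 genes (90 higher, 80 lower), and a fit of all 6 groups called 8. Of these 8, Lepr, the leptin receptor gene, was at 0.0618 ± 0.0314 CPM and 3.60 ± 0.980 CPM, and Pth1r, the parathyroid hormone receptor gene, was at 39.0 ± 13.7 CPM and 171.9 ± 39.0 CPM; Pth1r was chosen after its values were seen. In 1820 genes (12.1%; chance gives 10%) the libraries of the 2 ages did not overlap. In simulations with the spread of heart, edgeR recovered 54% of 4-fold changes, and 42.2% of DESeq2 calls were false.

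In brain, 1 gene, of antigen presentation, passed in the fit without a replicate term. H2-Q7 (ENSMUSG00000060550, GRCm38/mm10 chr17:35439155-35443773), a class I-like gene of the Qa region, rose from 8.36 ± 1.11 CPM to 54.2 ± 4.68 CPM (log2 2.70, SE 0.18; adjusted p 0.0209), with all 3 old libraries above all 3 young ones. Its near-identical neighbour H2-Q6 was at 24.0 ± 7.04 CPM and 127.5 ± 26.6 CPM (log2 2.41, SE 0.28; adjusted p 0.0827), and reads shared between the pair leave their separate levels uncertain. H2-K1, a classical class I gene, was at 604.5 ± 24.2 CPM and 811.8 ± 21.3 CPM. The 16 class I genes had a median of 0.26 (camera adjusted p 3.2e-10; adjusted p = 0.281 with an estimated correlation), and 3 passed adjusted over the list alone. H2-Ab1 of class II was at 4.24 ± 0.138 CPM and 10.4 ± 2.20 CPM.

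Genes of rapid stimulus response and of low oxygen were higher in old brain. Of 24 immediate early genes, 23 were higher (median 0.42; camera adjusted p 8.9e-13; adjusted p = 0.281 with an estimated correlation), and 11 passed adjusted over the list alone. Fos, an immediate early transcription factor gene that tissue digestion also induces, was at 5556 ± 371.0 CPM at 3 months and 8060 ± 847.1 CPM at 24 months (log2 0.54, SE 0.10). Btg2 was at 1421 ± 201.1 CPM and 2182 ± 135.9 CPM, and the nuclear receptor gene Nr4a1 at 2432 ± 374.3 CPM and 3692 ± 228.2 CPM. Of 25 glycolysis and hypoxia genes, 22 were higher (median 0.33; camera adjusted p 5.3e-10; adjusted p = 0.281 with an estimated correlation), and 8 passed adjusted over the list alone. Hif1a, the gene of the oxygen-sensing transcription factor, was at 186.0 ± 15.6 CPM and 329.2 ± 19.2 CPM (log2 0.82, SE 0.12). Bnip3, a hypoxia-induced mitophagy gene, was at 82.6 ± 9.24 CPM and 180.8 ± 82.9 CPM. In all of Fos, Btg2, Nr4a1, Hif1a and Bnip3 the 3 old libraries lay above the 3 young ones.

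Lists of clotting and barrier genes also passed camera with a preset correlation in brain, but not with an estimated one. Vwf, the gene of the clotting protein von Willebrand factor, was at 507.3 ± 86.6 CPM at 3 months and 1091 ± 131.0 CPM at 24 months (log2 1.10, SE 0.16; adjusted p 0.168), with all 3 old libraries above all 3 young ones. The haemostasis list of 19 genes was higher (median 0.27; camera adjusted p 0.0045; adjusted p = 0.281 with an estimated correlation), but its adjusted p was 0.0902 without library 2 of young brain and 0.0593 without library 1 of old brain. Of 22 blood-brain barrier genes, 17 were lower (median -0.14; camera adjusted p 0.00244; adjusted p = 0.447 with an estimated correlation), and the adjusted p was 0.0702 without library 2 of young brain. Mfsd2a, the lipid transporter, was at 714.3 ± 62.3 CPM and 435.8 ± 23.3 CPM (log2 -0.71, SE 0.11), and the tight junction gene Cldn5 at 2686 ± 176.1 CPM and 2111 ± 100.6 CPM. All 11 platelet genes were higher (median 1.99; camera adjusted p 2.6e-05; adjusted p = 0.447 with an estimated correlation), with a summed level of 22.4 ± 7.19 CPM and 69.98 ± 44.3 CPM. Library 2 of old brain held 19.9 CPM, among the young values of 14.4, 24.6 and 28.3 CPM. A split that mixed the ages gave this list a lower camera adjusted p, 1.1e-11. The leukocyte list summed to 153.0 ± 32.1 CPM and 222.0 ± 49.7 CPM.

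Over 14696 genes tested in brain, edgeR called H2-Q7 and 951 genes at an unadjusted p under 0.05 where chance gives 735. It called 0 when any 1 of the 6 libraries was left out, 2 with number 1 as a term, 0 among numbers 2 and 3 only, and 0 with the sequencing lane as a term. With the replicate number as a block it called 0, and H2-Q7 had a log2 of 2.70 (adjusted p 0.295). DESeq2 called 205 (149 higher, 56 lower) and a fit of all 6 groups called 24. Among these 24, Fmo1, a drug-metabolising enzyme gene chosen after its values were seen, was at 95.0 ± 2.29 CPM and 194.3 ± 14.4 CPM. The same fit called Fmo1 in kidney too, where it was at 74.5 ± 8.67 CPM and 168.0 ± 8.72 CPM. In 1931 genes (13.1%; chance gives 10%) the libraries of the 2 ages did not overlap. In simulations with the spread of brain, edgeR recovered 64% of 4-fold changes, and 36.8% of DESeq2 calls were false.

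In kidney, class II antigen presentation showed the clearest difference. H2-Ab1 (ENSMUSG00000073421, GRCm38/mm10 chr17:34257689-34269419) rose from 81.5 ± 4.998 CPM to 265.5 ± 29.4 CPM (log2 1.71, SE 0.14; adjusted p 0.0405), with all 3 old libraries above all 3 young ones. Cd74, the invariant chain gene of class II, was at 113.8 ± 28.9 CPM and 535.9 ± 63.3 CPM (log2 2.24, SE 0.22; adjusted p 0.0664), and H2-Eb1 at 19.4 ± 3.05 CPM and 72.8 ± 11.8 CPM. All 8 class II genes were higher (median log2 fold change 1.89; camera adjusted p 6.4e-43; adjusted p = 0.121 with an estimated correlation), 6 of 8 passed adjusted over the list alone, and fry gave an adjusted p of 0.0319. The leukocyte list summed to 60.8 ± 9.73 CPM and 103.2 ± 13.8 CPM. It passed as higher by camera with a preset correlation (adjusted p 0.0328) but not with an estimated one. The call was lost without library 3 of young kidney (0.114) or library 2 of old kidney (0.1605).

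Leukocyte adhesion genes were higher too. Sele (ENSMUSG00000026582, GRCm38/mm10 chr1:164048234-164057677), which encodes E-selectin, the endothelial protein that slows leukocytes, rose from 13.9 ± 1.70 CPM to 55.4 ± 3.11 CPM (log2 2.00, SE 0.17; adjusted p 0.0405), with all 3 old libraries above all 3 young ones. Selp, the P-selectin gene, was at 11.2 ± 2.53 CPM and 31.7 ± 11.6 CPM, and the chemokine gene Ccl2 at 0.453 ± 0.308 CPM and 4.15 ± 1.31 CPM. Of 22 adhesion and inflammation genes, 19 were higher (median 0.42; camera adjusted p 6.1e-08; adjusted p = 0.121 with an estimated correlation), and 5 passed adjusted over the list alone. The haemostasis list had a median of 0.40 (camera adjusted p 3.6e-06; adjusted p = 0.296 with an estimated correlation), and 8 of 20 genes passed adjusted over the list alone. Plat, the gene of tissue plasminogen activator, which dissolves clots, was at 1298 ± 177.5 CPM and 2526 ± 510.7 CPM. Plvap, the gene of the diaphragm protein of fenestrated vessels, was at 6702 ± 571.9 CPM and 10400 ± 1667 CPM. The pan-endothelial list summed to 11400 ± 399.8 CPM and 14730 ± 2445 CPM (camera adjusted p 7.9e-05; adjusted p = 0.460 with an estimated correlation). In old libraries 1 to 3 it summed to 16695, 15505 and 11992 CPM, beside 8449, 5998 and 12632 CPM for the renal tubule list. For Plat, Plvap and the haemostasis and adhesion lists, a larger endothelial share of the RNA was therefore not told apart from higher endothelial expression.

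Genes of mitochondrial respiration were lower in old kidney. All 7 tested genes of the mitochondrial genome were lower (median -1.23; camera adjusted p 1.0e-23; adjusted p = 0.121 with an estimated correlation), and 7 of 7 passed adjusted over the list alone. The cytochrome b gene mt-Cytb was at 7420 ± 776.8 CPM and 3162 ± 708.5 CPM (log2 -1.23, SE 0.18), and the complex I gene mt-Nd1 at 3223 ± 341.9 CPM and 1395 ± 317.7 CPM. All 48 nuclear genes of the respiratory chain were lower (median -0.44; camera adjusted p 1.7e-21; adjusted p = 0.376 with an estimated correlation), although 0 of 48 passed adjusted over the list alone, with 29 at an unadjusted p under 0.05. Cox7b, a cytochrome oxidase subunit gene, was at 82.6 ± 13.7 CPM and 46.4 ± 7.55 CPM. Tubule genes moved apart. Umod, the uromodulin gene of the thick ascending limb, was at 6502 ± 973.7 CPM and 3316 ± 1361 CPM. Slc34a1, the phosphate transporter gene of the proximal tubule, chosen after its values were seen, was at 37.5 ± 3.54 CPM at 3 months and at 245.9, 24.3 and 256.7 CPM in the old libraries. The tubule list did not pass (camera adjusted p 0.595; adjusted p = 0.842 with an estimated correlation) but passed without library 2 of old kidney (3.5e-22; adjusted p = 0.137 with an estimated correlation).

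Pericyte and smooth muscle genes were lower in old kidney as well, with a median of -0.97 over 14 genes (camera adjusted p 3.1e-08; adjusted p = 0.296 with an estimated correlation) and 5 of 14 past adjusted over the list alone. Myh11, the smooth muscle myosin gene, was at 112.8 ± 11.9 CPM and 36.7 ± 11.8 CPM (log2 -1.62, SE 0.25). The summed level of the list was 663.4 ± 90.3 CPM and 396.6 ± 86.6 CPM. As in heart, RNA of pericytes and smooth muscle cells was not told apart from endothelial expression. Circadian clock genes were higher (median 0.44; camera adjusted p 7.9e-05; adjusted p = 0.296 with an estimated correlation), with 2 of 17 past adjusted over the list alone, and the labels give no time of harvest. Hlf, a clock output gene, was at 9.35 ± 2.13 CPM and 30.5 ± 8.03 CPM. The rise of the clock list was not particular to kidney. With the preset correlation the list also passed as higher in heart (camera adjusted p 0.0283) and in brain (0.0134). Its summed level went from 1464 to 1963 CPM in heart and from 1630 to 1984 CPM in brain. In both of these organs the call was lost without certain single libraries.

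Over 16242 genes tested in kidney, edgeR called H2-Ab1 and Sele, with 1459 genes at an unadjusted p under 0.05 where chance gives 812. It called 0 without each of the 3 young libraries and without library 1 or 3 of old kidney, and 1, Slc34a1, without library 2 of old kidney. It also called 0 with number 1 as a term and 0 among numbers 2 and 3 only. With the replicate number as a block it called 0, and H2-Ab1 had a log2 of 1.70 (adjusted p 0.1905) and Sele of 2.00 (adjusted p 0.253). DESeq2 called 373 (206 higher, 167 lower) and a fit of all 6 groups called 5, H2-Ab1 among them but not Sele (adjusted p 0.673). In 2524 genes (15.5%; chance gives 10%) the libraries of the 2 ages did not overlap. In simulations with the spread of kidney, edgeR recovered 67% of 4-fold changes, and 12% of edgeR calls and 44.3% of DESeq2 calls were false.

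**Figure D2:**
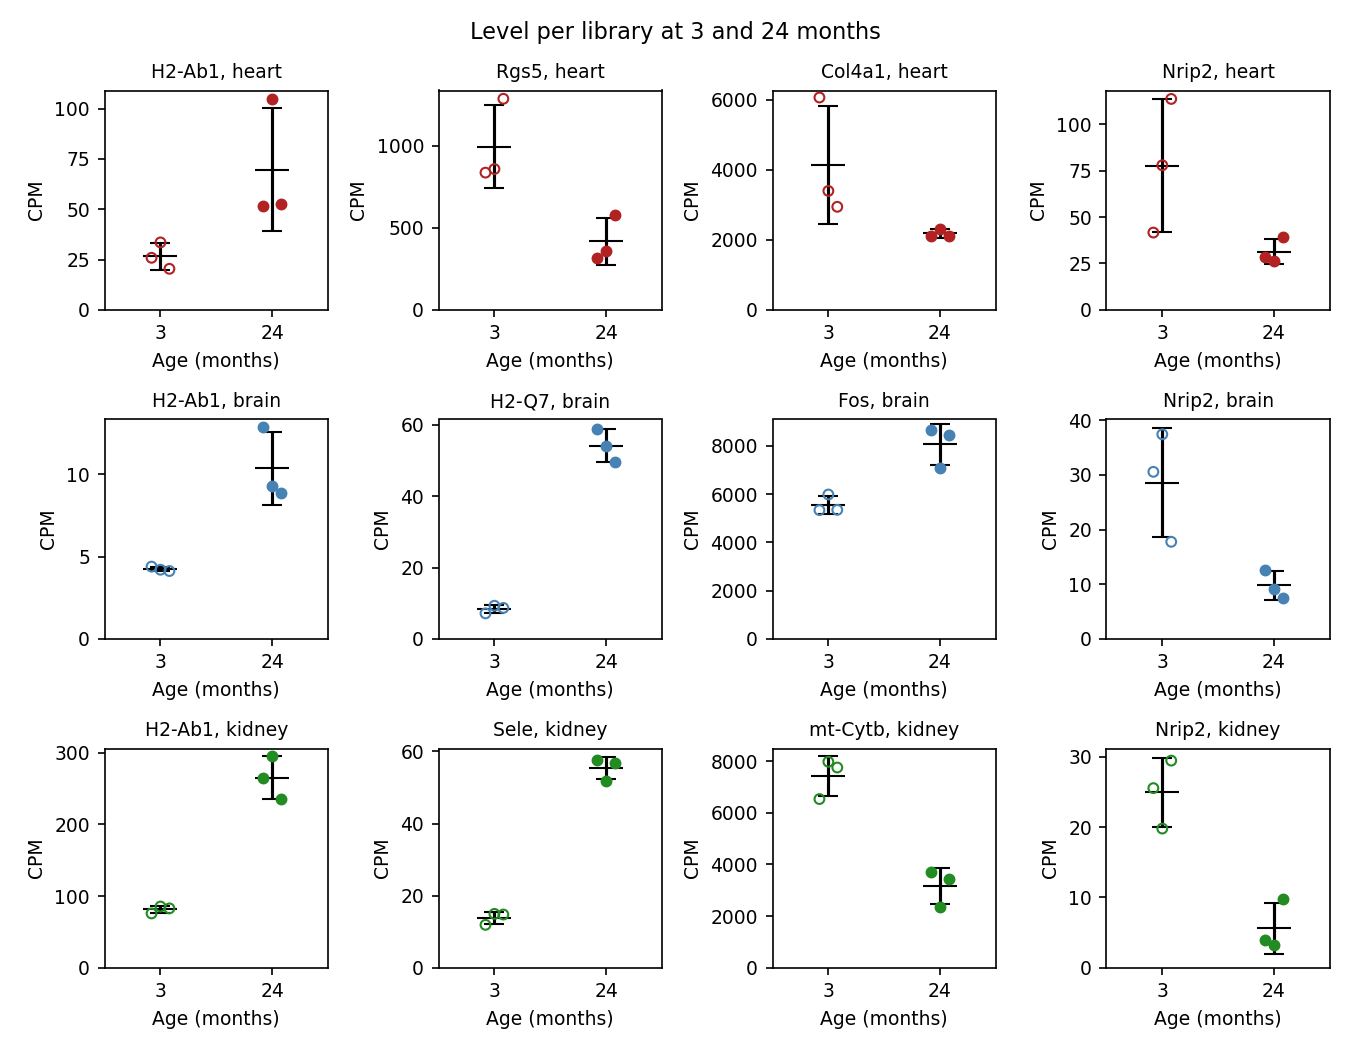
Level (CPM, y axis) of 4 genes in each organ, each circle a library at 3 months (open) or 24 months (filled), with a horizontal line at the mean and bars of 1 SD (n = 3). Kidney H2-Ab1 goes from 81.5 to 265.5 CPM and brain H2-Q7 from 8.36 to 54.2 CPM.

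**Figure D3:**
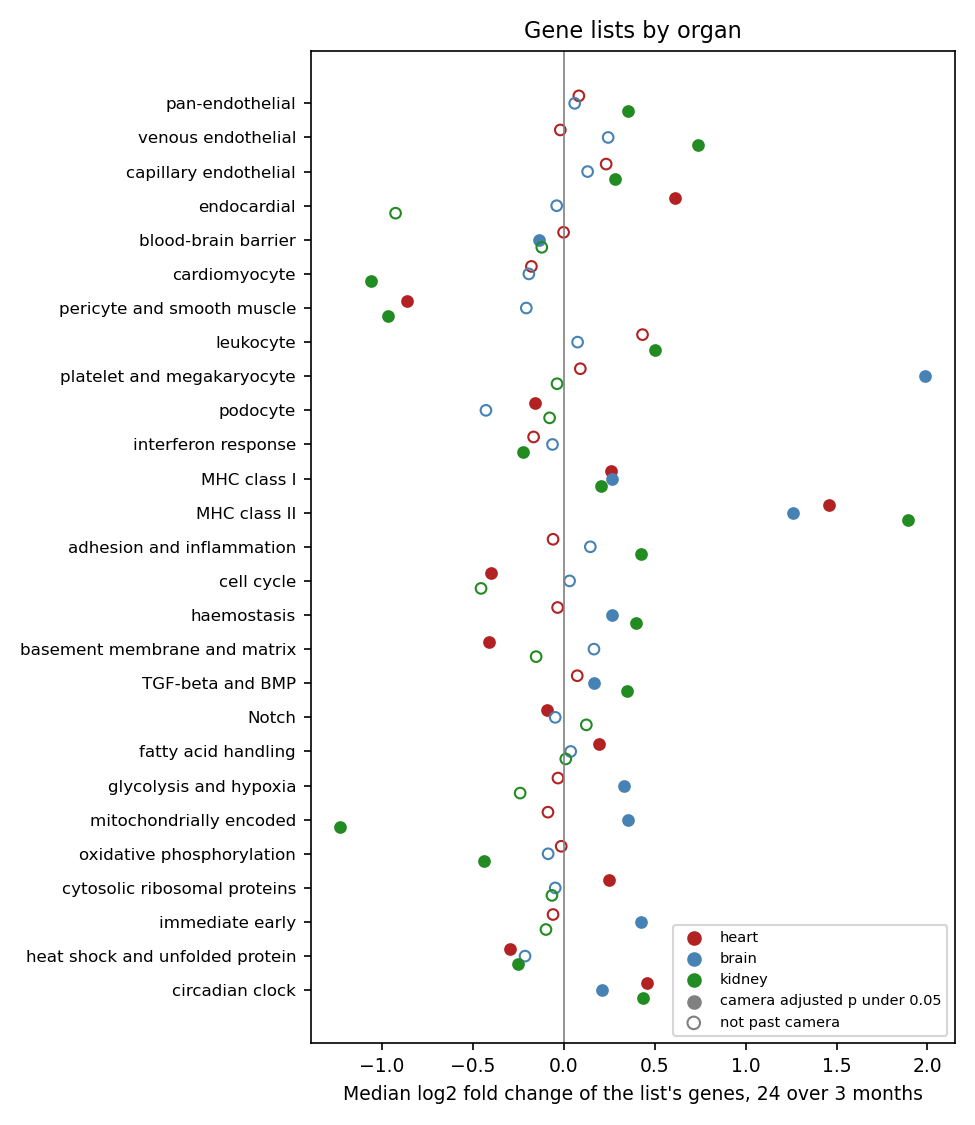
Median log2 fold change, 24 over 3 months (x axis), of 27 gene lists (y axis) in each organ, with filled symbols where camera with a preset correlation gave an adjusted p under 0.05. With an estimated correlation 0 lists passed in each organ.

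Over 46 lists per organ, camera with a preset correlation called 12 lists in heart (6 higher), 10 in brain (9 higher) and 16 in kidney (10 higher), and 0 in each organ with an estimated correlation. In brain 17 lists were called without library 1 at 3 months and 16 with number 1 as a term. Genes set in advance for cell ageing, endothelial function and sorting did not pass by edgeR in any organ, while DESeq2 called Vwf in brain (adjusted p 4.9e-08), as did edgeR on genes with a mean of at least 10 CPM (0.0479). Cdkn1a, the gene of the cell cycle inhibitor p21, was at 1151 ± 754.8 CPM and 1012 ± 587.2 CPM in heart, 1215 ± 451.4 CPM and 1391 ± 593.4 CPM in brain, and 484.8 ± 50.8 CPM and 538.7 ± 146.0 CPM in kidney. Nos3, the endothelial nitric oxide synthase gene, was at 477.8 ± 50.7 CPM and 456.9 ± 24.98 CPM in heart, at 545.6 ± 59.5 CPM and 539.0 ± 34.9 CPM in brain, and at 221.1 ± 13.8 CPM and 275.0 ± 64.5 CPM in kidney (log2 0.315, SE 0.181). Cdkn2a, the gene of the inhibitor p16, was at 0.617 ± 0.742 CPM and 2.29 ± 1.29 CPM in heart (log2 1.87), with overlapping libraries.

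Whether the age effect differed between organs was tested directly, as a difference of the 2 age effects in a fit of all 18 libraries, with levels scaled over all of them. Between heart and brain 11 genes passed (7 with the higher age effect in heart, 4 in brain), between heart and kidney 1, and between brain and kidney 9 (3 and 6). Lepr had a higher age effect in heart, 0.0606 ± 0.0310 CPM and 3.52 ± 0.949 CPM, than in brain, 53.4 ± 12.7 CPM and 67.6 ± 17.2 CPM (log2 difference 5.39, SE 0.53; adjusted p 0.000849), or than in kidney (5.35, SE 0.53; adjusted p 0.000927). Gpr160, an orphan receptor gene, went from 17.6 ± 2.75 CPM to 63.5 ± 16.2 CPM in heart and from 58.7 ± 8.93 CPM to 53.4 ± 9.06 CPM in brain (1.99, SE 0.28; adjusted p 0.0142). H2-Q7 had a higher age effect in brain than in kidney (log2 difference 2.10, SE 0.25; adjusted p 0.00434), where it was at 85.4 ± 9.33 CPM and 129.5 ± 2.72 CPM. Serpine2, the gene of a thrombin-inhibiting serpin, was at 112.1 ± 19.0 CPM and 51.1 ± 7.74 CPM in brain and at 240.5 ± 44.8 CPM and 639.2 ± 104.7 CPM in kidney (brain minus kidney -2.54, SE 0.29; adjusted p 0.00434). Among these genes Nat8f1, Scamp5, Tmigd1, Pidd1, Wdr35 and Chst1 had 0 to 2 counts over the 3 libraries of 1 group.

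By gene list with a preset correlation, the respiratory chain and the mitochondrial genome had a higher age effect in both other organs than in kidney, but not with an estimated one. For the respiratory chain the values were 3.7e-11 in brain (adjusted p = 0.544 with an estimated correlation) and 1.4e-13 in heart (adjusted p = 0.503 with an estimated correlation). The mitochondrial list had a higher age effect in brain than in kidney (camera adjusted p 7.0e-14; adjusted p = 0.151 with an estimated correlation) and in heart than in kidney (7.5e-08; adjusted p = 0.404 with an estimated correlation). Within brain the mitochondrial list passed as higher with age (camera adjusted p 0.00326), with sums of 3671 ± 92.0 CPM and 4947 ± 1286 CPM. That call was lost without library 1 or 2 of old brain (0.112 and 0.0810). The glycolysis and hypoxia list had a higher age effect in brain than in kidney (2.3e-10; adjusted p = 0.0724 with an estimated correlation). The pericyte and matrix lists had a lower age effect in heart than in brain (camera adjusted p 0.000202 and 1.9e-05; adjusted p = 0.414 with an estimated correlation for both). The counts of genes moved with single libraries. Between heart and brain the count was 3 without library 2 of young heart, or library 2 or 3 of old brain, and 7 without library 1 of young heart. Between brain and kidney it was 16 without library 3 of young brain or library 1 of old brain, and 5 without library 3 of old brain or library 1 or 3 of old kidney. Between heart and kidney it was 2 to 8 without library 2 or 3 of young heart, any library of old heart, library 1 or 2 of young kidney, or library 3 of old kidney, and 1 without each of the others.

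The overlap asks whether the organs age alike. In the main edgeR fits of each organ 0 genes passed in 2 organs. Fmo1 passed as higher in brain and kidney in the fit of all 6 groups (adjusted p 0.00157 and 0.00329). It also passed in both with the filter at a mean of 10 CPM. At an unadjusted p under 0.05, heart and brain shared 45 higher and 37 lower genes where independence gives 13.1 and 11.04. Heart and kidney shared 53 higher and 56 lower (16.98 and 17.9), and brain and kidney 65 higher and 29 lower (25.6 and 15.1). DESeq2 calls shared between organs with 1 direction numbered 9 for heart and brain, 13 for heart and kidney and 13 for brain and kidney. At an unadjusted p under 0.05 in all 3 organs with 1 direction, 24 of 13583 genes were found (12 higher, 12 lower) where independence gives 1.05, which is too low if libraries with 1 number share an animal. H2-Ab1 and Nrip2 were also called by DESeq2 in all 3 organs. Nrip2, the gene of a nuclear receptor-interacting protein, chosen after its values were seen, was at 77.8 ± 36.05 CPM and 31.5 ± 6.99 CPM in heart, 28.6 ± 9.99 CPM and 9.77 ± 2.64 CPM in brain, and 24.9 ± 4.86 CPM and 5.65 ± 3.62 CPM in kidney. Across genes the log2 fold changes correlated with r of 0.141 for heart and brain, 0.159 for heart and kidney and 0.191 for brain and kidney.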

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

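The splits of the libraries for counts of genes and lists and for pairs of organs were planned, while the tests of the class II, mitochondrial and replicate number patterns and the splits over 3 organs were chosen only after the results were seen. The genes listed first drew attention because their age effect differed between organs in the test of the difference itself. They are Lepr (adjusted p 0.000849 for heart minus brain and 0.000927 for heart minus kidney) and Gpr160 (0.0142), higher with age in heart. H2-Q7 (0.00877 for heart minus brain and 0.00434 for brain minus kidney) was higher with age in brain, and Map2 (0.0361 for heart minus brain) was at 2.27 and 7.72 CPM in brain and at 21.3 and 9.17 CPM in heart. Serpine2 (0.00434) and Prr5 (0.0266) had a lower age effect in brain than in kidney, Prr5 with 7.13 and 0.801 CPM in brain. The remaining calls have a group with 0 to 2 counts over 3 libraries, so their size is not given. For heart minus brain these were Nat8f1 (0.0279), Scamp5 (0.0142), Tmigd1 (0.0142), Pidd1 (0.0361), Wdr35 (0.0361), Chst1 (0.0279) and the predicted gene Gm37052 (0.0410). For brain minus kidney they were Pidd1 (0.0266), Wdr35 (0.0409), Chst1 (0.00549), Tmigd1 (0.00549), Scamp5 (0.00775) and Lrrc36 (0.0483).

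For these differences, 100 assignments of the ages within organs were counted, the real one included. As many genes as the real 11 were reached in 8 of 100 for heart minus brain (highest other 23) and as many as the real 1 in 74 of 100 for heart minus kidney (highest other 9), so chance is not excluded there. For brain minus kidney 3 of 100 reached the real 9 (highest other 13), fewer than the 5 of 100 set in advance. These assignments ignore the replicate number, and the share is not corrected for the 3 differences tested, so chance is not excluded there either. With the number within each age as a block, 6 genes were called for heart minus brain, 3 for heart minus kidney and 4 for brain minus kidney. Of the genes named by the rule, 5 of 9 for heart minus brain and 4 of 8 for brain minus kidney then no longer passed.

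With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The number of splits as large as the real one, the real one included, was as follows. For edgeR it was 10 of 10 in heart (real 0, highest other 0), 1 of 10 in brain (real 1, highest other 0) and 1 of 10 in kidney (real 2, highest other 0). For DESeq2 it was 1 of 10 in heart (170, highest other 97), 2 of 10 in brain (205, highest other 280) and 1 of 10 in kidney (373, highest other 145). The brain split with 280 set libraries 1 and 2 at 3 months and 1 at 24 months against the rest, which is not the split by sequencing lane. For lists by camera it was 3 of 10 in heart (12, highest other 15), 2 of 10 in brain (10, highest other 10) and 3 of 10 in kidney (16, highest other 19). For organs at 3 months it was 1 of 10 each, with 2466, 3407 and 3700 genes and highest others of 1, 4 and 1. Among the lists called with age, the real split gave the lowest adjusted p for 5 of 12 in heart, 5 of 10 in brain and 10 of 16 in kidney. Splits that mixed the ages went lower for example for class I (0.000222) and cell cycle (2.4e-09) in heart. They also did for platelets (1.1e-11) and the barrier (0.00123) in brain and for the pan-endothelial list (2.2e-05) in kidney.

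For genes shared between organs, 100 pairs of splits were drawn. By edgeR 100 of 100 reached the real 0 in each of the 3 pairs of organs (highest other 0), which says nothing. By DESeq2 1 of 100 reached the real 9 of heart and brain (highest other 4), 1 of 100 the real 13 of heart and kidney (highest other 5) and 1 of 100 the real 13 of brain and kidney (highest other 6). Chance was thus excluded only for splits drawn apart, which ignore the replicate number. For the 24 genes at an unadjusted p under 0.05 in 3 organs, splits drawn apart for each organ gave 1 of 100 (highest other 11). The same split by number applied to every organ gave 1 of 10 (highest other 20), too few for a share under 0.05. The highest value of 20 in a split by number shows that libraries of different organs with 1 number share part of their variation, so this count over 3 organs cannot be read as ageing alone. For the pairs of organs by DESeq2, the same split by number in both organs shared at most 2, 4 and 3 genes, against the real 9, 13 and 13. These are again 10 splits, too few for a share under 0.05.

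The class II genes of kidney were higher at 24 months by a median log2 of 1.89. RNA of leukocytes was weighed first: 14 leukocyte genes had a median of 0.5 (SD over the genes 1.02), below the class II median by more than that spread. This argues against a rise of all these leukocyte genes alike as the whole source. The list was itself higher by camera with a preset correlation (adjusted p 0.0328), with Cd14, C1qa, C1qc and Lyz2 as its genes of lowest p. A median over genes of several leukocyte types cannot exclude a rise of 1 type that carries class II. Cd74, the most abundant class II gene, reached 535.9 CPM while the whole leukocyte list summed to 103.2 CPM. How much Cd74 RNA such cells carry was not measured, so these sums do not decide it. The sort removed CD45 positive cells. Thinning every kidney library to the smallest total left the median at 1.907. Thinning keeps the expected share of each gene, so it could show only added counting noise and does not decide on library size. Leukocyte types whose markers were not in the list were not tested, though the sort against CD45 applies to them as well, and an effect of age on endothelial class II expression stays open as untested.

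The mitochondrial genes of kidney were lower at 24 months by a median log2 of -1.23, and kidney tubules, rich in mitochondria, may have left RNA in the sorted cells. Less RNA of all tubule segments was tested with 17 tubule genes, whose median was 1.374 (SD over the genes 1.49), on the other side and farther off than that spread, which argues against a loss of all segments alike. Leaving out 1 library in turn gave medians of 1.142 to 1.960, and without library 2 of young kidney the SD of 2.81 reached the mitochondrial median. Values of single libraries go the other way in part. In old library 2, with the lowest mitochondrial sum (5876 CPM), the tubule median was -0.742 against 1.529 and 1.559 in libraries 1 and 3, so such a loss stays open there. The tubule sum also fell, from 12920 ± 789.1 CPM to 9026 ± 3354 CPM, and camera turned to lower without old library 3 (adjusted p 0.132). Less RNA of the thick ascending limb, marked by Umod, remains open. The mitochondrial median minus the Umod change was -0.259, within the Umod SE of 0.274, so the 2 changes were alike in size. The prediction for this test also named Slc12a1, whose change is not given here, so this likeness rests on 1 gene. The ratio of mitochondrial to Umod counts was 3.34, 3.27 and 2.78 at 3 months and 3.01, 2.66 and 2.01 at 24 months. An effect of age on mitochondria of endothelial cells cannot be told apart from it, since tubule RNA and endothelial RNA are mixed in the same libraries.

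Libraries with 1 replicate number varied together across groups. The mean correlation, across 14092 genes, of same-numbered libraries of different organs as deviations from their group means was 0.085, reached by 2 of 1296 renumberings (highest other 0.087), and that of the 2 ages of an organ was 0.092, reached by 2 of 216 (highest other 0.097), which is consistent with a shared day, or for organs a shared animal, behind each number. The sequencing lane alone was tested with same-numbered libraries that share no lane. Their median correlation was 0.074 for 13 pairs of organs (lowest 0.026) and 0.068 for 3 pairs of ages (lowest 0.065), above 0 throughout, which argues against it as the whole source. For the 143 genes that differed between the numbers, 1 of 100 renumberings within groups gave as many (highest other 121). Glucocorticoid hormones, which stress before harvest raises, were weighed because Zbtb16 (log2 2.57, SE 0.14; adjusted p 1.2e-05), Fkbp5 (2.40) and Tsc22d3 (0.86) were higher in number 1. A list of 15 genes, 4 of which had been seen in the pattern, gave a mean correlation of 0.921, reached by 12 of 1296, and without those 4, left out after this result was seen, 11 genes gave 0.262, reached by 220 of 1296 (highest other 0.898). The same 11 genes were higher in number 1 than in the others (median log2 0.278; camera p 6.6e-05; p = 0.0226 with an estimated correlation), and their score was highest in number 1 in 5 of 6 groups, the exception being old kidney. A hormone response therefore stays open, since these tests disagree and genes seen to differ had been left out. The 143 genes also held clock genes, with Arntl higher in number 1 (log2 1.52) and Dbp (-1.29) and Tef (-0.85) lower. Chaperone genes such as Stip1 (1.58) and Hsp90ab1 (1.02) were among the higher ones. No test was run for these groups of genes, so the hormone response is not the only lead. Apart from the hormone response no biological explanation of the numbers was tested, since the labels do not say what the numbers share.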

How the results depend on the processing

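The filter at a mean of 10 CPM, limma voom, the terms for number 1 and for the lane, numbers 2 and 3 only, and leaving out libraries for lists and overlap were chosen after seeing the data; the cause was not tested unless stated. Organ comparisons stayed within 1.5 times the reported count under each alternative run (DESeq2 3397, 4297 and 4520).

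Counts of genes with age moved as follows. DESeq2 gave 170 in heart, 205 in brain and 373 in kidney. The joint fit of 6 groups gave 8, 24 and 5. With the replicate number as a block, brain and kidney gave 0, and a block gave 6, 3 and 4 differences between organs. In kidney, no filter gave 7 and the filter at 1 CPM gave 7, runs kept as separate replicates gave 16, since runs of 1 library then count as replicates, and the other pair of the labels summed 48, which also merges 2 libraries. A mean of at least 10 CPM gave 11 in brain and 13 in kidney, with fewer genes tested. Number 1 as a term gave 2 in brain and 0 in kidney, numbers 2 and 3 only gave 0 in both, and the lane as a term gave 0 in brain. Leaving out 1 library gave 0 to 0 in heart and brain and 0 to 1 in kidney (Slc34a1 without library 2 of old kidney). For differences DESeq2 gave 277, 198 and 192. Leaving out 1 library gave 3 to 16, 1 to 8 and 5 to 16. Shared genes by DESeq2 numbered 9, 13 and 13.

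For lists, an estimated correlation gave 0 in each organ and fry 0, 0 and 1. In brain, leaving out 1 library gave 9 to 17 and number 1 as a term 16.

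Of the values of named genes under the alternatives, 3645 kept direction and side, 104 came to pass, 114 no longer passed and 32 changed direction, none of these past the threshold. A value that passed in neither fit also counts as keeping its side. With age, edgeR called only 0, 1 and 2 genes in heart, brain and kidney, so the 3645 do not measure how stable calls were. H2-Q7, H2-Ab1 and Sele no longer passed in any fit that left out 1 library of their organ. Leaving out 1 library gave these log2 ranges, which cross 0. In heart they were -2.431 to 0.333 for Hsph1, -6.623 to 0.433 for Ptprc, -0.752 to 0.479 for Cdkn1a and -0.114 to 0.026 for Nos3. In brain they were -0.002 to 0.209 for Pecam1, -1.359 to 2.053 for Ptprc, -0.194 to 0.531 for Cdkn1a and -0.082 to 0.068 for Nos3. In kidney they were -0.680 to 0.365 for Cdkn2a, -1.038 to 0.081 for Ptprc, -0.065 to 0.677 for Vwf, -0.070 to 1.550 for Pdpn and -0.089 to 0.303 for Cdkn1a. Cdkn2a of kidney also changed direction to 0.441 with the number as a block, 0.001 with runs kept as separate replicates, 0.162 with only 1 run of the repeated library, 0.110 with the other pair summed, 1.093 with voom and 0.451 with number 1 as a term. Numbers 2 and 3 only turned Hsph1 of heart to 0.147, Ptprc to 1.005 in heart and 0.558 in kidney, and Nos3 of brain to 0.050, which the lane as a term put at 0.029. Voom put Ptprc of brain at 0.291, and separate runs put Cdkn1a of heart at 0.015.

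Of the list values, 342 were the same, 7 came to pass, 131 no longer passed and 4 changed direction. Leaving out 1 library gave adjusted p of 0.1285 to 0.8287 for the leukocyte list of heart, 6.2e-07 to 0.415 for the heat shock list of heart and 3.5e-22 to 0.791 for the tubule list of kidney. They changed direction at 0.560, 0.415 and 0.132, and the ribosomal list of heart did with numbers 2 and 3 only, at 0.844. In simulated counts with the spread of each organ, edgeR recovered 16% to 25% of 2-fold age changes and DESeq2 40% to 52%; depth was not varied.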

Other observations

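No test in this part was chosen after a result was seen, apart from the filter at a mean of 10 CPM and the choice of Rasgrf2 and Sox4 after their values were seen. In brain, Rasgrf2 and Sox4, which are outside the lists, were not called by the main edgeR fit within the organ but were by DESeq2 and by the joint fit of 6 groups. With the filter at a mean of 10 CPM edgeR within the organ called Rasgrf2 but not Sox4. Rasgrf2, an exchange factor gene of Ras signalling, was at 9.65 ± 2.07 CPM (SD, n = 3) at 3 months and 44.5 ± 7.45 CPM at 24 months, with an edgeR adjusted p of 0.0827 (DESeq2 2.6e-13; joint fit 0.000564) and all 3 old libraries above all 3 young ones. Sox4, a transcription factor gene of developing cells, was at 46.3 ± 13.5 CPM and 17.8 ± 1.73 CPM (adjusted p 0.237; DESeq2 0.000107; joint fit 0.00863), with all 3 old libraries below all 3 young ones.

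In kidney, the list of TGF-beta and BMP genes was higher by camera with a preset correlation and not with an estimated one. Eng, a TGF-beta co-receptor gene also held by the pan-endothelial list (camera adjusted p 7.9e-05; adjusted p = 0.460 with an estimated correlation), was at 1022 CPM at 3 months and 1545 CPM at 24 months, and Bmper, a regulator of BMP signals, at 7.88 CPM and 23.1 CPM. The TGF-beta and BMP list had a median of 0.35 over 32 genes (camera adjusted p 0.000507; adjusted p = 0.296 with an estimated correlation), and 1 of 32 passed adjusted over the list alone. As for the adhesion list of kidney, a larger endothelial share of the RNA was not told apart from higher endothelial expression.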
